A study of Oryza sativa with 10 samples.

How the data were processed

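Total RNA from rice roots was sequenced, per the labels' protocols, in 2 lines with and without NaCl, and 10 libraries were used. The authors deposited a file per library with raw read counts per gene, not normalized, for 38978 genes, together with the chromosome, start, end, strand and length of each gene's exons, per the file headers. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, featureCounts and DESeq2 were used with the genome build IRGSP-1.0; their versions and settings are not given in the sources used here. The tissue rests on the labels alone: no nuclear marker gene could be named, so it was not checked whether the libraries hold root RNA, and each value is that of libraries labelled root. No column of another sample was present, and the number of such columns was 0.

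Whether the counting used strand was looked at in the values. Exon bases were shared by 5918 pairs of genes, 5764 of them on opposite strands, which involved 11453 genes or 29.4%. Of 112 pairs on opposite strands that shared at least 90% of their bases and had a mean count of at least 100, all 112 had counts within 10% of each other, against 6.1% of random pairs. Reads in such overlaps were therefore counted for both genes without regard to strand, and genes that overlap another cannot be told apart from it by these counts. Each comparison was repeated with 1 gene per set of overlapping genes, joined where they shared at least 0.5 of the shorter gene's exon bases, and positions on chromosomes were analysed on such sets alone.

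Groups came from the sample titles and characteristics: S13 control (n = 2), S13 salt (n = 3), S3 control (n = 2) and S3 salt (n = 3). Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group removed 10789 genes and left 28189, TMM factors scaled the libraries, and a quasi-likelihood model with 4 group means and no block was fitted to all libraries. The TMM factors were 1.31 to 1.42 in control and 0.729 to 0.922 in salt libraries. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. The 5 contrasts were salt against control in each line, S13 against S3 under each condition, and the difference of the responses. The biological coefficient of variation was 37.3% over all groups and 25.2%, 46.2%, 32.5% and 35.3% within S13 control, S13 salt, S3 control and S3 salt. CPM values given for genes are TMM-scaled, whereas shares of counts and the search for loci with reads in 1 line only use library totals. Library totals of 22938524 to 25703942 counts put a floor of 3 counts at 0.117 to 0.131 CPM in a library; floors cover counting error only. Replicates of a group differed by 36.9 to 224 times the sampling variance (chi-square per degree of freedom), so none was treated as a repeat of another.

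On simulated counts with 200 of 28189 genes changed, the test recovered 0% of 2-fold changes in each contrast. For 4-fold changes it recovered 29.5% and 34.5% in the salt contrasts of S13 and S3, 15.5% and 51% between the lines without and with salt, and 0.5% for the difference of the responses. For 8-fold changes these shares were 69.5%, 67.5%, 64%, 77% and 40%. In the data the salt contrasts called 27.1% and 32.8% of genes in S13 and S3. The adjusted threshold was therefore less strict there than with 200 changed genes, and the simulated shares may be too low for them. Of 7627 genes called for salt in S13, 6994 differed by at least 2-fold, so changes under 2-fold were called too. The statistic on neighbouring loci was also tested on simulated calls.

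Before the data were examined, a rule for the genes to be named, 35 gene lists, a panel of 20 salt genes, the tests and most of the other settings tried were fixed. Of 37849 nuclear identifiers in the files, the reference table of gene names (assembly ASM3414082v1) paired 1 with a name and none with a description. The panel (0 of 20 paired) and 33 of the 35 lists therefore could not be used. The list meant for cytosolic ribosomal proteins matched 32 plastid and mitochondrial genes and was not used under that name. The photosystem list matched 15 plastid genes. Names in the text are those of 112 organelle genes, 59 plastid and 53 mitochondrial, that the files name themselves; 109 of them are also in the reference table. By the rule, the named genes are the 6 with the largest rise and the 6 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap of the compared libraries, and up to 4 members of each list. Without the requirement of a name, the same rule gave the nuclear identifiers, at most 2 in each direction. Groups of organelle genes other than the photosystem list, and the further organelle genes given as examples, were chosen after the data were seen.

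Gene groups were tested with camera and fry in limma 3.58.1. Alternatives were DESeq2 1.42.0, limma-voom, DESeq2 size factors in edgeR, no filter or a filter of 5 CPM in at least 2 libraries, fits on the compared groups alone, a replicate block, a 2-fold threshold and the omission of each library in turn. Fits with 1 gene per overlapping set, library totals without TMM factors, the correlation of the line differences and the count of neighbours without loci that share exon bases were added after the data were seen. The other tests on neighbouring loci, with 1 gene per overlapping set, were written down beforehand. Called loci were counted in windows of 1 Mb with at least 10 tested loci among 24246 tested nuclear loci, with an exact one-sided hypergeometric test. Neighbouring calls were compared with 1000 shuffles of the calls within deciles of expression. These steps and the figures used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.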

Results

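Gene expression was measured by RNA sequencing of rice (Oryza sativa) roots, as the labels give the tissue, in a line labelled salt tolerant (S13) and a line labelled salt susceptible (S3). The plants were 42 days old and had spent the last 12 days in 140 mM NaCl or, as controls, in 0 mM NaCl. Each line had 2 control libraries and 3 salt libraries, so that 10 libraries fell into 4 groups. The libraries held between 22938524 and 25703942 counts over 38978 genes. The control libraries detected between 30693 and 31829 genes and the salt libraries between 29913 and 30877. Nothing in the labels says whether the libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

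Treatment separated the libraries along the leading principal component, which held 46.9% of the variance, and line separated them along the next component, which held 20.4%. A handful of genes took a larger share of the counts under salt. The 10 most abundant genes of a library held 7.73% ± 0.621 (SD, n = 2) of its counts in S13 controls and 12.4% ± 2.04 (SD, n = 3) in S13 under salt. In S3 these shares were 6.85% ± 1.20 (SD, n = 2) and 12.8% ± 1.64 (SD, n = 3). Of the 25 most abundant genes, 5 lay within the interval from 15223376 to 15343671 on chromosome 11 of IRGSP-1.0, and together they held 4.56% ± 0.586 (SD, n = 2) of the counts in S13 controls against 7.53% ± 1.65 (SD, n = 3) under salt. In S3 the same region held 3.57% ± 1.20 (SD, n = 2) and 7.78% ± 1.22 (SD, n = 3). This region was chosen after its values were seen.

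**Figure D1:**
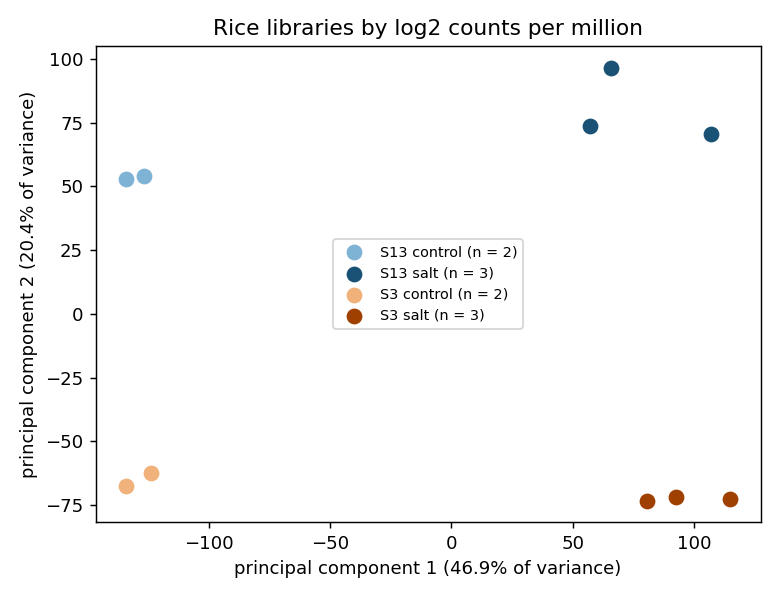
Each point is a library, placed by the leading (x axis, 46.9% of the variance) and following (y axis, 20.4%) principal components of log2 CPM, in arbitrary units, and coloured by group. The 4 control libraries lie on the left, the 6 salt libraries on the right, S13 lies above 0 and S3 below it on the y axis.

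The first comparison asks what salt changed in the line labelled tolerant, in libraries labelled root. Of 58 tested plastid genes with a name, 31 were higher and 3 lower under salt in S13, against 3613 higher and 4014 lower of all 28189 genes. As a group they passed in camera with a preset correlation of 0.01 and not with an estimated one (Benjamini-Hochberg adjusted p = 9.41e-12 and 0.380), and they passed in fry, which tests against no change (adjusted p = 0.0381). Without the first S13 control library 15 were higher and without the second 11. The strongest rise was that of rpoB, which encodes a subunit of the plastid RNA polymerase. It went from 0.657 ± 0.238 (SD, n = 2) to 24.2 ± 7.34 (SD, n = 3) CPM (counts scaled by library size and TMM factor), a log2 fold change of 5.19 ± 0.61 (SE). The plastid genes atpA, for a subunit of the ATP synthase, and psbA, for a reaction centre protein of photosystem II, went the other way. Expression of psbA was 68.1 ± 44.8 (SD, n = 2) CPM in controls and 13.3 ± 2.58 (SD, n = 3) under salt.

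The named genes of 1 stretch of the plastid genome, chosen after its values were seen, were all higher. Between 19214 and 32885 of the plastid genome lie, among others, the named genes rpoB, rpoC1, rpoC2, rps2, atpI, atpH and atpF, and each of them was higher under salt, with log2 fold changes from 2.50 for rpoC2 to 5.19 for rpoB. The next gene along, atpA, had a log2 fold change of -2.65 ± 0.42 (SE) with an adjusted p of 0.00265 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. The other plastid genes with the largest rises were atpF, rps12, petE, rps2 and atpH, with log2 fold changes of 5.13, 4.51, 4.46, 4.46 and 4.34. The models of atpF, rps12 and petE span only 145, 114 and 114 bp of exon in the files, so their values rest on short stretches. For rpoB and these 5 genes every salt library lay above both control libraries, which the rule for naming genes required.

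Of the 15 tested genes of the photosystem list, which was fixed before the data were examined as a marker of green tissue, 6 were higher and 2 lower in S13, and adjusted over the list alone 9 were higher and 2 lower. The genes psbE, psbF and psbK, which encode small subunits of photosystem II, had log2 fold changes of 2.95 ± 0.42, 2.71 ± 0.43 and 3.02 ± 0.57 (SE). The gene psaC, for the iron-sulphur subunit of photosystem I, had a log2 fold change of -2.17 ± 0.51 (SE), which became -1.01 and was no longer past the threshold without the first S13 control library. In camera at the preset correlation the list was higher (Benjamini-Hochberg adjusted p = 0.00198), and with an estimated correlation the adjusted p = 0.384, and in fry 0.0720. Without the second S13 control library 3 of its genes were higher and the camera adjusted p at the preset correlation was 0.0895. All named plastid genes together had a median log2 fold change of 1.69. Named plastid genes held 0.0436% ± 0.0232 (SD, n = 2) of counts in controls and 0.0442% ± 0.00989 (SD, n = 3) under salt, so their joint share did not differ by more than the spread between libraries. All counts on the plastid genome, most of them outside named genes, were 0.168% ± 0.0168 (SD, n = 2) and 0.307% ± 0.0289 (SD, n = 3). Of 31 tested mitochondrial genes with a name, 9 were higher and 0 lower, among them cob, for cytochrome b, with a log2 fold change of 2.04 ± 0.37 (SE), and atp9, with 1.78 ± 0.43 (SE). Without the first S13 control library 0 of these were higher, without the second 1, and without the third S13 salt library 4. With library totals in place of TMM factors 20 plastid genes were higher and 4 lower, and 1 mitochondrial gene was higher. The 9 mitochondrial genes higher in the main fit had few counts. Their means in S13 controls ran from 0.0458 CPM for nad6, below the floor of 3 counts in a library, to 3.00 for atp1.

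Over all 28189 tested genes, 3613 were higher and 4014 lower under salt in S13 by the edgeR quasi-likelihood test, and 6994 of these 7627 differed by at least 2-fold. The nuclear genes carry identifiers that the sources used here do not pair with names, so only a few are given. Os08g0262500 (chromosome 8, 9921522 to 9923218) had 0 counts in both S13 controls and 8.60 ± 1.18 (SD, n = 3) CPM under salt, at least 188-fold higher against a floor of 3 counts over the group. This gene also had 0 counts in the S3 control and S3 salt libraries, so its reads came from S13 salt libraries only. Os08g0473800 (chromosome 8, 23340677 to 23342603), which shares exon bases with another gene, was at 0.642 and 0.306 CPM in the controls and at 27.8, 757 and 10.9 under salt; it did not pass without either control library or with limma-voom. Os04g0612301 (chromosome 4, 31051207 to 31051503) was at 39.0 and 5.11 in the controls with 1 count over the salt libraries. Os02g0814200 (chromosome 2, 34889675 to 34893873) was at 38.4 and 16.1 in the controls with 2 counts over the salt libraries. The split depended on the scaling: with library totals instead of TMM factors 1375 genes were higher and 10004 lower, and the median log2 fold change of all genes moved from -0.03 to -0.76. Without the first S13 control library 1503 genes were called and without the second 2467.

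**Figure D2:**
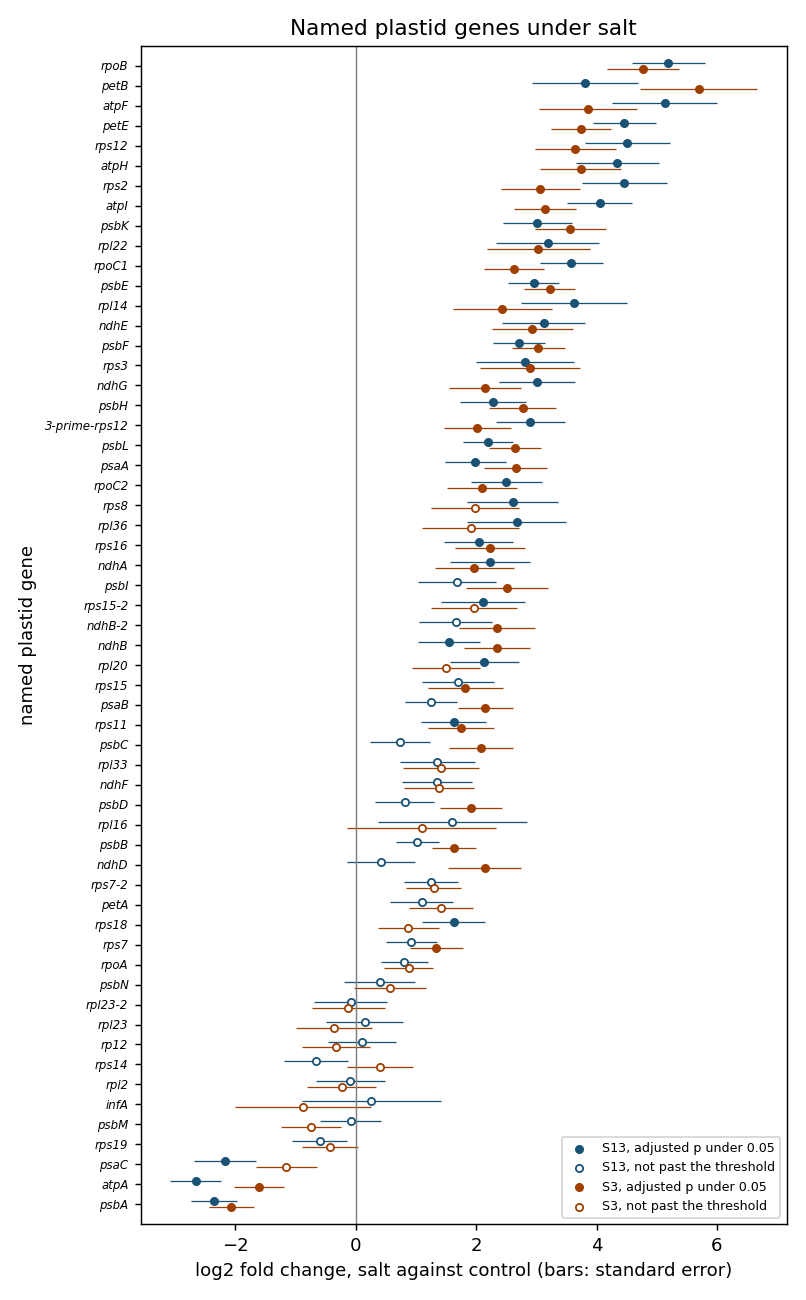
Log2 fold change of each of the 58 tested plastid genes with a name (x axis) under salt against control, with standard errors as bars, in S13 (blue) and S3 (brown); filled points passed an adjusted p of 0.05. Genes are sorted by the mean of both lines, from psbA, atpA and psaC at the bottom to rpoB at the top.

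In the line labelled susceptible, 35 of 58 named plastid genes were higher under salt and 2 lower. Without the first S3 control library 19 were higher and without the second 16. The leading gene was petB, whose model in the files holds 6 bp of exon, with a log2 fold change of 5.69 ± 0.97 (SE). It was followed by rpoB, from 0.680 ± 0.161 (SD, n = 2) to 18.7 ± 11.1 (SD, n = 3) CPM, with a log2 fold change of 4.77 ± 0.59 (SE). The genes petE, atpH, rps12 and psbK had log2 fold changes of 3.75, 3.74, 3.65 and 3.57. The 7 named genes from rpoB to atpF on the plastid genome were again higher, and psbA (-2.06 ± 0.38, SE) and atpA (-1.60 ± 0.41, SE) were lower. The fold change of atpA was -1.32 without the first S3 control library and -1.46 without the second S3 salt library, and did not pass in either case.

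Of the photosystem list, 11 of 15 genes were higher and 1 lower in S3, with the same counts adjusted over the list alone. Without either S3 control library 6 were higher. In this line psbC, psbD, psaB, psbB and psbI passed the threshold, with log2 fold changes of 2.08, 1.91, 2.15, 1.63 and 2.52. In S13 their log2 fold changes were 0.74, 0.82, 1.25, 1.02 and 1.68, and they did not pass. There psaB, psbB and psbI came close (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0535, 0.0543 and 0.0766). The test of the difference between the lines' responses did not call the 5 genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.617, 0.667, 0.682, 0.749 and 0.822). The list had a camera Benjamini-Hochberg adjusted p of 4.92e-05 at the preset correlation, 0.340 with an estimated correlation and 0.0347 in fry. The gene psaC had a log2 fold change of -1.15 ± 0.51 (SE) and did not pass. Named plastid genes held 0.0376% ± 0.0121 (SD, n = 2) of counts in controls and 0.0501% ± 0.0191 (SD, n = 3) under salt, and all plastid counts 0.177% ± 0.0162 (SD, n = 2) and 0.350% ± 0.0928 (SD, n = 3). Of 31 mitochondrial genes 6 were higher and 0 lower, among them cob (1.81 ± 0.37, SE) and cox3 (2.00 ± 0.51, SE), both of the respiratory chain. Without either S3 control library 2 were higher. Without TMM factors 22 plastid genes were higher and 4 lower, and 3 mitochondrial genes were higher. The 6 mitochondrial genes higher in the main fit had means in S3 controls from 0.0305 CPM for nad6 to 2.08 for cob.

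Over all tested genes 4059 were higher and 5178 lower in S3 by the edgeR quasi-likelihood test, and 8359 of these 9237 differed by at least 2-fold. Os02g0186100 (chromosome 2, 4791404 to 4793451) had 1 count over the controls and 81.4, 63.4 and 18.9 CPM under salt. Os01g0917100 (chromosome 1, 39985223 to 39986495) had 3 counts over the controls and 10.4, 71.9 and 37.9 CPM under salt. Neither gene passed without either control library or with limma-voom. Os03g0591700 (chromosome 3, 21954147 to 21957702) was at 12.8 ± 2.19 (SD, n = 2) CPM in controls and at 0 counts under salt, at least 255-fold lower. Os10g0557600 (chromosome 10, 21944314 to 21945183), which shares exon bases with another gene, was at 19.5 ± 1.30 (SD, n = 2) in controls with 2 counts over the salt libraries. With library totals instead of TMM factors 1636 genes were higher and 10407 lower. Leaving out the first S3 control library left 3224 calls, the second 5277, and the second S3 salt library 5965.

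The salt responses of the lines, which share no library, followed each other gene by gene. Of the genes called in both lines 2357 were higher in both, 2837 were lower in both and 4 went opposite ways. With library totals instead of TMM factors 754 were higher in both and 7449 lower in both. For the main lists, independent lists of these sizes would share 520, 737 and 1242. Across the 28189 genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.738. The leading principal axis of the fold changes had a slope of 0.95 (S13 per S3), which is not the slope of a regression of S13 on S3.

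**Figure D3:**
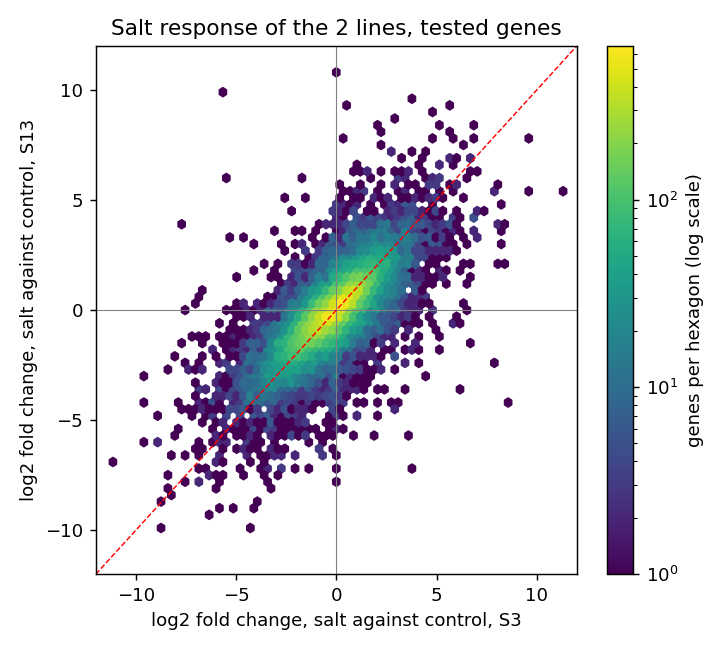
Tested genes by log2 fold change under salt in S3 (x axis) and in S13 (y axis), binned into hexagons whose colour gives the number of genes on a log scale. The dashed line marks equal change; the Pearson correlation across genes is 0.738.

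Without salt, the largest differences between the lines were at loci with 0 counts in 1 of them. Whether such a locus was silent, absent or too divergent for its reads to map was not examined. Os12g0299300 (chromosome 12, 11904703 to 11907272) was at 96.1 ± 11.9 (SD, n = 2) CPM in S13 controls and had 0 counts in S3, at least 2011-fold higher against a floor of 3 counts over the group. Os06g0147100 (chromosome 6, 2457429 to 2458126) was at 79.2 ± 23.96 (SD, n = 2) against 0 counts, at least 1657-fold. The other way round, Os07g0642100 (chromosome 7, 26719124 to 26727238) was at 29.8 ± 5.68 (SD, n = 2) in S3 and Os10g0212100 (chromosome 10, 8070371 to 8074802) at 23.9 ± 3.24 (SD, n = 2), both with 0 counts in S13, which allows ratios of at least 650 and 521. No named plastid or mitochondrial gene was called between the lines, in a contrast that recovered 15.5% of 4-fold changes in simulated counts.

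In all, 213 genes were higher and 188 lower in S13 than in S3 controls, and each of these 401 differed by at least 2-fold. The called loci lay in groups on the chromosomes. With 1 gene per set of overlapping genes, 26% of 366 called loci had a neighbour called in the same direction, against a mean of 1.53% and a highest value of 4.92% in 1000 shuffles within classes of expression (permutation p = 0.001, the smallest they can give). Without loci at 0 counts in 1 line, 206 called loci remained and 12.1% had such a neighbour. Of 375 windows of 1 Mb, 24 held more called loci than the rest of the genome by an exact hypergeometric test with Benjamini-Hochberg adjustment. On chromosome 1, from 20000001 to 21000000, 9 of 46 tested loci were called, and on chromosome 12, from 12000001 to 13000000, 8 of 36. By DESeq2 846 genes were called and with a stricter filter 246. Without the first S13 control library the count was 255, and without the first or second S3 control library it was 230 or 246.

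Under salt, too, the largest differences between the lines were at loci with 0 counts in 1 of them. Os06g0147100 and Os06g0146800, which lie together on chromosome 6 (2449205 to 2449822 for the latter), were at 520 ± 474 and 414 ± 297 (SD, n = 3) CPM in S13 and at 0 counts in S3, at least 10410-fold and 8287-fold higher. The S13 salt libraries held 242, 1067 and 252 CPM of the former and 272, 756 and 215 of the latter, so the second library raised both folds. Os09g0337300 (chromosome 9, 10252139 to 10254682) was at 95.1 ± 35.7 (SD, n = 3) in S3 and Os09g0256700 (chromosome 9, 4277193 to 4277778) at 41.9 ± 8.73 (SD, n = 3), both with 0 counts in S13, at least 1896-fold and 836-fold. No named plastid gene passed the test between the lines, and the photosystem list had a median log2 fold change of -0.38 with a camera Benjamini-Hochberg adjusted p of 0.233, which was 0.0277 without the second S3 salt library, 0.0459 with the stricter filter and 0.996 with an estimated correlation.

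Salt libraries gave 506 genes higher and 499 lower in S13 than in S3, and 994 of these 1005 differed by at least 2-fold. Here 27.7% of 888 called loci had a neighbour called in the same direction, against at most 6.87% in the shuffles, and 718 of the called loci remained without loci at 0 counts in 1 line. The windows with more calls than elsewhere numbered 27, and 15 of them were among the 24 of the control libraries, where independent sets would share 1.73. The window on chromosome 12 from 12000001 to 13000000 held 13 called loci of 36, and that on chromosome 6 from 16000001 to 17000000 held 11 of 35. Of genes called both with and without salt, 184 were higher in S13 in both, 154 lower in both and 1 went opposite ways, against 3.82, 3.33 and 7.14 for independent lists. Across genes the line differences of the control and the salt libraries, which share no library, correlated with r = 0.644. The count was 587 without the first S13 salt library, 1978 without the second, and 590 or 530 without the first or second S3 salt library. DESeq2 called 1893 genes, the stricter filter 634, and a fit on the salt libraries alone also 634.

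**Figure D4:**
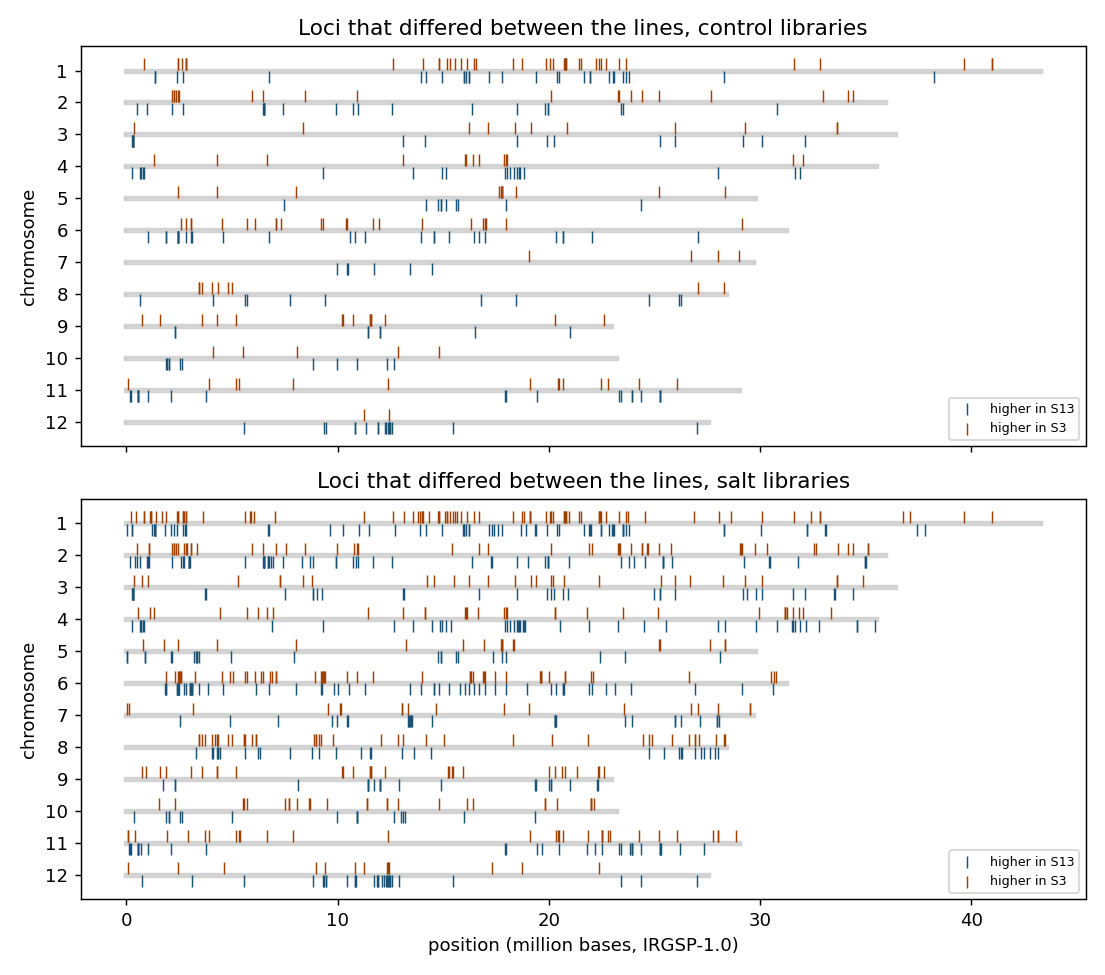
Position on the 12 chromosomes (x axis, Mb of IRGSP-1.0; y axis, chromosome) of loci called between the lines in the control (top) and salt (bottom) libraries, with 1 gene per overlapping set. Blue ticks are loci higher in S13 and brown ticks loci higher in S3; of 375 windows of 1 Mb, 24 (control) and 27 (salt) held more calls than elsewhere.

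The last comparison asks whether the lines responded differently to salt. No gene, nuclear or organellar, passed the threshold for the difference between the S13 and the S3 response. The edgeR quasi-likelihood test called 0 genes, with a lowest Benjamini-Hochberg adjusted p of 0.125. Where a locus had 0 counts in all libraries of a line, that line's response cannot be estimated, so the test cannot decide on such a locus. Os08g0262500, for example, had 0 counts in all S3 libraries. In S13 it had 0 counts in controls and 8.60 ± 1.18 (SD, n = 3) CPM under salt. At an unadjusted p under 0.05 there were 2435 genes, where 1409 are expected by chance. limma-voom called 0 genes and DESeq2 142. The gene with the lowest p, Os06g0696500 (chromosome 6, 29137112 to 29138074), was chosen after its values were seen. It was at 0.871 ± 0.454 (SD, n = 2) and 20.1 ± 1.07 (SD, n = 3) CPM in S13 without and with salt, and at 4.91 ± 0.687 (SD, n = 2) and 6.28 ± 1.01 (SD, n = 3) in S3.

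The photosystem list had a median difference of -0.55 between the log2 responses, and 1 of its 15 genes was above 0. Its camera Benjamini-Hochberg adjusted p was 0.109, and the adjusted p = 0.931 with an estimated correlation. At the preset correlation it was 4.5e-05 without the second S13 control, 0.0208 without the third S13 salt, 0.0178 without the first S3 control and 0.0125 without the second S3 salt library, and 0.0179 with the stricter filter. Without the first S13 control library the median of the list was 0.10 and the adjusted p = 0.971. All named plastid genes had a median difference of -0.05 with a camera adjusted p of 0.752 at the preset correlation. That median became 0.75 without the first S13 control library, -0.48 without the second and -0.58 without the first S3 control library, so its direction changed with single libraries. In simulated counts this contrast recovered 0.5% of 200 genes changed 4-fold and 40% of 200 changed 8-fold among 28189 genes, so most differences of 4-fold would be missed. Without the second S13 control library 9 genes were called, and without the second S13 salt library 3.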

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

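Most results kept their direction and their side of the threshold. Of the alternatives for named genes and gene groups, 1289 did so, 37 lost the call and 20 gained it. In 47, all of gene groups, the median log2 fold change turned sign, and in 43 of these neither fit passed the threshold. Of those for the counts and correlations, 36 moved and the others stayed within the bounds set for totals, which say nothing of directions. The causes were not tested except where stated. The 1289 include groups that passed neither in the main fit nor in the alternative. With the estimated correlation no gene group passed in camera for salt (lowest Benjamini-Hochberg adjusted p = 0.380 in S13 and 0.340 in S3). Fits with library totals without TMM factors, fits with 1 gene per overlapping set and the correlation of the line differences were chosen after the data were seen.

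Between the lines under control DESeq2 called 846 genes and the stricter filter 246, and under salt DESeq2 called 1893, the stricter filter 634 and the fit on the compared libraries 634. The stricter filter tests fewer genes. For the difference of the salt response DESeq2 called 142. The correlation of the salt responses was 0.5752 without a filter, 0.8002 with the stricter filter and 0.7883 on the compared libraries. That of the line differences was 0.5459 with limma-voom, 0.461 without a filter and 0.6954 with the stricter filter. With library totals the calls for salt turned mostly downward, 1375 higher and 10004 lower in S13 and 1636 and 10407 in S3.

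Leaving out each library in turn gave 1503 to 7748 calls for salt in S13 and 3224 to 11131 for salt in S3. For the lines it gave 230 to 506 without salt and 530 to 1978 with salt, and for the difference of the responses 0 to 9. The correlations ranged from 0.6447 to 0.7445 for salt and from 0.5305 to 0.6481 for the lines. A control group reduced to 1 library was assumed to vary like the other groups.

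Medians of gene groups also ranged across 0 when libraries were left out in turn. For S13 against S3 under control they ran from -0.5847 to 0.7255 for all named plastid genes, -0.357 to 0.5385 for the photosystem list, -0.5595 to 0.8331 for ndh genes, -0.6699 to 1.008 for plastid and -0.2876 to 0.3992 for mitochondrial ribosomal proteins, and -0.4508 to 0.9763 for nad genes. The median of the plastid genes went both ways: -0.5847 without the first S13 control library, 0.5624 without the second and 0.7255 without the first S3 control library. In the main fit their estimated inter-gene correlation was 0.712, far above the preset 0.01. With the estimated correlation their camera Benjamini-Hochberg adjusted p was 0.880. Under salt the medians ran from -0.06512 to 0.5615 for all named plastid genes, -0.2954 to 0.4839 for ndh genes, -0.2258 to 0.219 for mitochondrial ribosomal proteins, -0.2668 to 0.1323 for all named mitochondrial genes and -0.02735 to 0.3072 for genes with an ENSRNA identifier. For the difference of the responses they ran from -0.576 to 0.7497 for all named plastid genes, -0.868 to 0.09942 for the photosystem list, -0.7368 to 0.6918 for ndh genes, -0.5575 to 1.029 for plastid and -0.3074 to 0.4888 for mitochondrial ribosomal proteins, -1.446 to 0.1262 for nad genes and -0.05065 to 0.266 for all named mitochondrial genes. For salt in S3 the ENSRNA genes ranged from -0.1516 to 0.01561.

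With the replicate block the difference of the responses was 0.08843 for all named plastid genes and 0.08582 for ndh genes, against -0.05285 and -0.03133 in the main fit. With library totals the ndh genes were at -0.06017 between the lines under salt, and the ENSRNA genes at -0.5519 for salt in S13, against 0.1904 in the main fit, while the median of all genes moved to -0.762. The ENSRNA genes passed there in camera at the preset correlation (Benjamini-Hochberg adjusted p = 0.00379), and in the main fit they did not (0.167). With the stricter filter the ENSRNA genes were at 0.7973 for salt in S3, against -0.07479. This passed in camera (Benjamini-Hochberg adjusted p = 0.00126), and the main value did not.

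With the replicate block 6110 and 8372 genes were called for salt in S13 and S3, 338 and 838 between the lines without and with salt, and 0 for the difference. Deviations of libraries with the same number correlated at -0.122 to 0.199, so the numbers were not taken to pair the samples. With 1 gene per overlapping set the counts were 6651, 8166, 375, 893 and 0.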

Other observations

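Tests chosen only after the results were seen are those on all named plastid genes, on the splits of the salt libraries, on the other organelle groups, on the line-specific loci and on neighbours without any shared exon base, and the fits with library totals; those on the photosystem list and the other tests on neighbouring loci were written down beforehand.

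Some nuclear loci gave reads in every library of 1 line and none in the other. With a CPM of at least 1 on library totals in all 5 S13 libraries and 0 counts in all 5 S3 libraries there were 55 such loci, with 1 gene per overlapping set, and 33 the other way round. By treatment, 2 loci had reads in the control libraries only and 0 in the salt libraries only. Such loci within 200 kb of each other were joined into runs. The run with the most loci lay on chromosome 6 from 2446226 to 2458126, where 4 loci had reads in S13 only. On chromosome 4 from 661317 to 837306 and from 18478742 to 18619467, and on chromosome 12 from 12377948 to 12472828 there were 3 each with reads in S13 only, and on chromosome 1 from 20783516 to 20820444 there were 3 with reads in S3 only.

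Genes with 1 exon made up a larger share of the genes that rose under salt, and of those called between the lines, than of all tested. They made up 28.9% of 2940 loci higher and 18.4% of 3587 loci lower in S13, and 26.4% of 3363 and 17.2% of 4639 in S3, against 22.8% of all 24246 tested nuclear loci. Between the lines they made up 34.8% of loci higher and 32.7% of loci lower in S13 without salt, and 27.1% and 28.5% with salt. No test was run on these shares.

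Loci that differed between the lines lay next to each other, which may reflect technical or inherited differences. Reads counted for overlapping genes do not account for it, since with 1 gene per overlapping set 27.7% of loci called under salt had a called neighbour, against at most 6.87% in the shuffles. Such sets leave smaller overlaps in place, but without any locus that shares exon bases with another gene the share was still 24.3%, against at most 7.15%. Of loci called for salt, 38.1% in S13 and 44.5% in S3 also had a called neighbour, against at most 28.2% and 33.6% in the shuffles. That excess was smaller: the shuffle means were 25.9% and 31.5% there. Between the lines the shares were 26% without and 27.7% with salt, against shuffle means of 1.53% and 3.65%. Windows with more calls in either direction numbered 1 and 0 for salt in S13 and S3. For the lines they numbered 24 without and 27 with salt, of 375. Loci without any read in 1 line do not account for all of it either: without them the share was 21.6%, against at most 5.71%. An inherited difference between the lines predicted that the windows recur in other libraries, and 15 of the 24 windows of the control libraries recurred under salt. Partial loss of reads where a line's sequence departs from the reference would recur in the same way and stays open, because no reads or variants were used here.

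Of 58 named plastid genes 31 were higher and 3 lower under salt in S13, and 35 and 2 in S3, psbA and atpA being lower in both. As a group they did not pass in camera with an estimated correlation (Benjamini-Hochberg adjusted p = 0.380 and 0.340) but passed in fry against no change (0.0381 and 0.0347), and 2 technical explanations were set against the treatment. A larger share of plastid RNA that raised all plastid transcripts alike is argued against by their spread: 50% of the 58 genes in S13 and 41.4% in S3 lay over 2 standard errors from their median. The share of all plastid counts, most of them outside named genes, did rise, from 0.168% to 0.307% in S13 and from 0.177% to 0.350% in S3. That of the named genes was 0.0436% ± 0.0232 (SD, n = 2) and 0.0442% ± 0.00989 (SD, n = 3) in S13. In S3 it was 0.0376% ± 0.0121 (SD, n = 2) and 0.0501% ± 0.0191 (SD, n = 3). In neither line did the share of the named genes differ by more than the spread between libraries. Green tissue need not raise all plastid transcripts alike, so the spread cannot decide on a larger share of it. TMM factors alone are argued against by the fit with library totals, in which the median log2 fold change of the plastid genes was 0.91 in S13 and 1.28 in S3. A change in plastid RNA share together with changes of individual genes may remain, as does an effect of the salt treatment itself, which was not tested apart from it.

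For S13 against S3 under salt the 6 libraries can be split into equal groups in 10 ways, too few for a share under 0.05. In a fit on these libraries the real split called 634 genes and the highest of the others 0, so that 1 split of the 10 reached the real count.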
